A study of Mus musculus with 6 samples.

How the data were processed

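The series holds 6 RNA-seq libraries of mouse left ventricle, 3 labelled TAC and 3 labelled Sham, in a gene table of 34745 genes and a lncRNA table of 43234 transcripts. Per the labels' protocols, total RNA was purified with an miRNeasy kit, treated with DNase and made into libraries with a VAHTS total RNA kit. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.0 and the genome build GRCm38 (mm10). The role of each tool, the annotation version, the counting program, its strand setting and any filter are not given in the sources used here. Each library was tied to its group by the column name that its description label gives, and no value column lacked a library.

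The deposited tables hold, per the file headers, a count and an FPKM value per library. The counts deposited by the authors are whole numbers with library totals of 17399510 to 28401399 over genes (1.63 times apart) and 1547100 to 2397057 over lncRNA transcripts. The FPKM values deposited by the authors for genes divide each count by a length and by the library's total gene count. Those for lncRNAs use a library total 1.016 to 1.024 times as large, and that total served as the lncRNA library size. Mitochondrially encoded genes took 12.0% to 16.0% of the gene counts, and Ttn, the titin gene, 7.37% to 8.81%. In every library Xist had 3 to 7 counts and Ddx3y at least 1496. Replicate libraries differed by far more than counting noise, with a chi-square per gene of at least 16.7 within a group.

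Because the tables held counts, the test planned for counts was used: edgeR 4.0.16 quasi-likelihood, TMM scaling, filterByExpr with its minimum count of 10, no block, Benjamini-Hochberg adjustment, adjusted p under 0.05, in R 4.3.3. It was run on each table alone. SEs of single genes and transcripts are the absolute log2 difference divided by the square root of the F statistic. An SE given with a median over genes is the SD over those genes divided by the square root of their number. It measures the spread between genes, not between libraries. Levels are TMM-scaled CPM, counts divided by the scaled library size, as mean ± SD over 3 libraries. Fold differences are those fitted by edgeR. Intervals for ratios of lncRNA counts are exact Poisson intervals, which cover counting error only. The 40 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Symbols were matched to the gene table directly (644) or through a table of gene IDs (5), and 7 were not in the gene table. Lists with at least 3 tested members, 39 of the 40, were tested with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry, which tests whether the genes of a list move on balance in 1 direction, adjusted over the lists. Adipocyte markers had too few tested members. With an estimated correlation no list was past the threshold, and the smallest adjusted p was 0.126. The directional fry test was past it for 2 lists, matrix proteins and activated fibroblast markers (adjusted p = 0.0460 for both).

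The genes named are Nppa, Nppb, Myh7, Myh6, Acta1 and Atp2a2, genes from the 10 largest differences per direction among genes past the threshold with a mean FPKM of at least 1 and groups that do not overlap, and up to 4 members with the smallest p of each list described. Predicted symbols, pseudogenes and clone names (read as having no symbol) were left out of the second part. Other passing members were named where 5 or fewer passed. For lncRNAs the 5 largest differences per direction were named, at a mean FPKM of at least 0.5. The pseudogene type came from RefSeq (GRCm38.p6) by symbol and chromosome. Coordinates are those of the deposited tables.

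The alternatives were limma 3.58.1 on log2(FPKM + 0.1), with pseudocounts of 1 and 0.01, without the trend, robust, with array weights and after quantile normalization, whose fold differences lie on that log2 scale. They also included mean FPKM filters of 0.1 and 5, no filter, median-of-ratios scaling, totals without mitochondrial genes, a replicate block, a 2-fold minimum and each library left out. DESeq2 1.42.0, totals without TMM and KEGG terms of the deposited table (one-sided Fisher tests, 300 terms of 10 to 300 tested genes) were added after seeing the data.

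The test was checked on simulated data for this comparison, with the means, library sizes and dispersions of each table and 10 draws of 200 changed features. Over 15198 genes it recovered 46.4% of 2-fold and 87.9% of 4-fold changes, and 7.63% of its calls were false. Over 16035 lncRNA transcripts it recovered 0 of the 2-fold and 12.1% of the 4-fold changes, and 17.1% of its calls were false. Whether the simulated counts hold transcripts that switch between high and almost absent, as the real lncRNA table does, was not checked. There were 25 false lncRNA calls over the 10 draws. With the real libraries split 3 against 3 in other ways, the test called 3 to 15 transcripts per split, so the real false share may be higher.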

Results

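Total RNA was sequenced from the left ventricle of male C57BL/6 mice, a common inbred strain, given as 8 weeks old in the labels. The mice had undergone transverse aortic constriction (TAC), in which a ligature narrows the aortic arch so that the left ventricle pumps against a raised pressure, or a sham operation without the ligature, and the tissue was taken 6 weeks later. 3 libraries carry the label TAC and 3 carry the label Sham. The counts over genes summed to 21489237, 20075844 and 19810439 in the libraries labelled TAC 1, 2 and 3, and to 20650648, 28401399 and 17399510 in those labelled Sham 1, 2 and 3. The counts over long non-coding RNA (lncRNA) transcripts summed to between 1547100 and 2397057 per library. Nothing in the labels says that each library came from a separate mouse, so the p-values measure the spread between these libraries.

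The comparison asked which genes and lncRNAs differ in the left ventricle between chronic pressure overload and sham surgery. Several genes known to be raised in the pressure-overloaded ventricle were higher in the libraries labelled Sham, while Nppb and Myh7, given below, did not pass the test. Nppa, which encodes atrial natriuretic peptide, had 1087 ± 704 CPM (library-scaled counts; SD, n = 3) in the libraries labelled Sham and 83.9 ± 17 in those labelled TAC, a difference of 13-fold (8.13-fold without the library labelled Sham 2). Acta1, the skeletal alpha-actin of the fetal heart programme, stood at 3791 ± 1080 against 403 ± 263 CPM, 9.41-fold higher in the libraries labelled Sham. The fitted log2 differences, labelled TAC minus labelled Sham, were -3.70 (SE 0.45) for Nppa and -3.23 (SE 0.56) for Acta1, with adjusted p = 0.0222 and 0.0448 in edgeR's quasi-likelihood test. Because this direction goes against the labels, the groups are called the libraries labelled TAC and the libraries labelled Sham throughout, and every direction given here is that of the labels.

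All 9 hypertrophy and fetal-programme genes had a lower estimate in the libraries labelled TAC, and 4 passed the test: Nppa, Acta1, the actin-binding protein gene Xirp2 (4.90-fold, adjusted p = 0.0396) and the ankyrin repeat gene Ankrd1 (3.87-fold, adjusted p = 0.0492). Adjusted over the list alone, 6 passed. The median log2 difference was -1.61, and the list differed from other genes with a preset correlation (camera adjusted p = 6.21e-11). The call was lost with an estimated correlation (adjusted p = 0.31). Nppb, the gene of brain natriuretic peptide, had 251 ± 149 CPM in the libraries labelled Sham and 83.5 ± 55.6 in those labelled TAC and did not pass (log2 difference -1.59, SE 0.60, adjusted p = 0.191; -0.998 without the library labelled Sham 2). Myh7, the slow beta-myosin heavy chain, did not pass either (log2 difference -0.69, SE 1.37, adjusted p = 0.814). Its counts were 212, 65.7 and 6050 CPM in the libraries labelled TAC 1, 2 and 3 and 1816, 6323 and 2072 CPM in those labelled Sham 1, 2 and 3. Without the library labelled TAC 3 its log2 difference was -4.61 (adjusted p = 0.0843), and without the library labelled Sham 2 it was 0.12 (adjusted p = 0.984). On all 6 libraries it was between -3.88 and -2.66 with limma and -2.92 with the replicate number as a block, so it also depended on the method. Over the settings that gave one, the adjusted p ran from 0.0673 to 0.984. Myh6, the alpha-myosin heavy chain of the adult mouse ventricle, had 29710 ± 3730 CPM in the libraries labelled TAC and 18250 ± 5170 in those labelled Sham (log2 difference 0.70, SE 0.23, adjusted p = 0.152). Myh6 and Myh7 have similar sequences, and how reads shared between them were assigned is not given in the sources used here. Atp2a2, the calcium pump of the sarcoplasmic reticulum, had 14910 ± 460 against 10620 ± 2050 CPM (log2 difference 0.49, SE 0.17, adjusted p = 0.173).

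**Figure D1:**
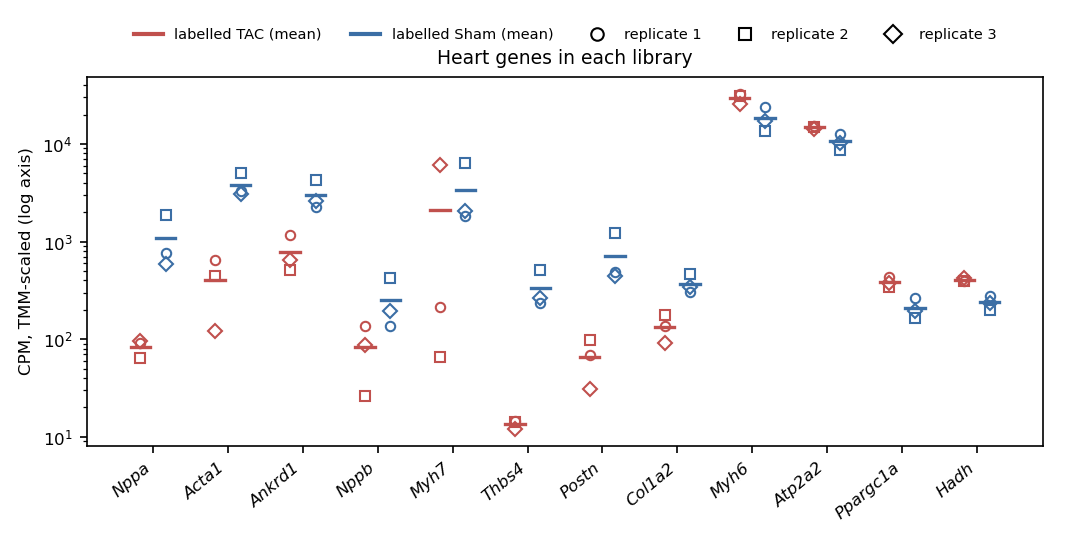
TMM-scaled CPM on a log axis for 12 heart genes, with a symbol for each library, labelled TAC in red and labelled Sham in blue, and a bar at the mean of each group of 3. Nppa, Acta1, Ankrd1, Thbs4, Postn and Col1a2 were higher in each library labelled Sham than in each library labelled TAC, while Myh7 reached 6050 CPM in the library labelled TAC 3.

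Over the whole gene table, 217 of 15198 genes tested passed an adjusted p of 0.05, 168 higher in the libraries labelled Sham and 49 higher in those labelled TAC. With library totals left unscaled by TMM the split was 296 and 42, with quantile normalization 92 and 37, with DESeq2 712 and 483, and with the replicate number as a block 40 and 1. Of the 168, 138 differed by at least 2-fold, and of the 49, 23 did so. The first principal component (44.9% of the variance) parted the labelled groups, and the second (21.8%) set the library labelled TAC 3 apart from the other 5. In 27.0% of the genes tested the groups did not overlap, all 217 among them, against 10% by chance for 3 against 3. The count changed when 1 library was left out. It was 0 without the library labelled TAC 1 (2564 genes at an unadjusted p under 0.05), 10 without TAC 2 and 22 without TAC 3. It was 397 without Sham 1, 24 without Sham 2 and 40 without Sham 3. Such fits hold fewer libraries, so a lower count cannot be told apart from lost power. DESeq2, run on all 6 libraries, called 1195.

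Most of the largest differences belonged to extracellular matrix genes. Thbs4, which encodes thrombospondin-4 (chromosome 13, 92751590 to 92794818 on GRCm38), had 337 ± 150 CPM in the libraries labelled Sham and 13.6 ± 1.31 in those labelled TAC, 24.8-fold apart (log2 difference -4.63, SE 0.32, adjusted p = 0.00792). Ltbp2, a latent TGF-beta binding protein gene, was 18.8-fold higher in the libraries labelled Sham and Spp1, the osteopontin gene, 17.8-fold. Comp, the cartilage oligomeric matrix protein gene, followed at 13.8-fold, Cilp at 11.8-fold, Postn, which encodes periostin, at 11.0-fold, Wisp2 at 10.5-fold and Col12a1 at 9.93-fold. Together with Nppa these were among the 10 largest differences in that direction at a mean FPKM of at least 1, with edgeR adjusted p-values from 0.00792 to 0.0372. Spp1 stood at 10.6-fold without the library labelled Sham 3, Comp at 24.8-fold without TAC 3 and Postn at 7.10-fold without Sham 2, where Postn no longer passed (adjusted p = 0.0729).

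Matrix genes were higher in the libraries labelled Sham as groups. All 29 non-collagen matrix proteins and cross-linkers had a higher estimate in the libraries labelled Sham, 15 passed over all genes and 25 passed adjusted over the list alone (median log2 difference -2.07, camera adjusted p = 6.75e-45; adjusted p = 0.126 with an estimated correlation). Among those that passed were Thbs4, Ltbp2, Cilp and Wisp2. Of the 19 collagens, all had a higher estimate in the libraries labelled Sham, 4 passed (Col12a1, Col5a2, Col16a1 and Col1a2) and 16 passed adjusted over the list alone (median -1.30, camera adjusted p = 1.07e-19; adjusted p = 0.289 with an estimated correlation). Col1a2, a chain of type I collagen, had 371 ± 87.6 CPM in the libraries labelled Sham and 134 ± 42.3 in those labelled TAC. Of 15 matrix proteases and inhibitors, Mmp23 passed (2.25-fold) and 11 passed adjusted over the list alone (camera adjusted p = 7.96e-09; adjusted p = 0.289 with an estimated correlation). Mmp2 (adjusted p = 0.0588), Adamts2 (adjusted p = 0.0813) and Timp1 (adjusted p = 0.0991) had negative log2 differences of -1.20, -1.10 and -3.18, that of Timp1 being -4.11 without the library labelled TAC 1 and -2.56 without Sham 3.

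Markers of activated fibroblasts were the group with the largest median. 6 of 10 passed, all higher in the libraries labelled Sham, including Thbs4, Cilp, Itgbl1 and Comp, and 9 passed adjusted over the list alone, 8 of them in that direction (median log2 difference -2.87, camera adjusted p = 5.20e-21; adjusted p = 0.126 with an estimated correlation). 4 of these 10 genes are also in the list of matrix proteins. None of the 10 general fibroblast markers passed over all genes, and 5 passed adjusted over the list alone, 4 of them higher in the libraries labelled Sham (median -0.35, camera adjusted p = 0.0197; adjusted p = 0.345 with an estimated correlation). This list was no longer past the threshold without the library labelled TAC 1 (adjusted p = 0.0699) or Sham 1 (adjusted p = 0.229). In the list of TGF-beta family signalling, 2 of 19 genes passed, Tgfb3 (1.89-fold) and Ltbp3 (1.89-fold), both higher in the libraries labelled Sham, and 8 passed adjusted over the list alone, 7 of them in that direction (camera adjusted p = 0.000477; adjusted p = 0.345 with an estimated correlation). Tgfb2 was at adjusted p = 0.0505 with a log2 difference of -2.04, and Tgfbr1 at 0.0932 with -1.03.

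Genes of oxidative metabolism had higher estimates in the libraries labelled TAC. Of 26 genes of fatty acid uptake and oxidation, 25 had a positive log2 difference and Hadh, which encodes hydroxyacyl-CoA dehydrogenase of mitochondrial beta-oxidation, passed over all genes (1.71-fold, adjusted p = 0.0488), with 405 ± 19.6 CPM in the libraries labelled TAC and 238 ± 40.4 in those labelled Sham. Adjusted over the list alone, 21 passed (median log2 difference 0.55, camera adjusted p = 6.47e-14; adjusted p = 0.329 with an estimated correlation). Acaa2 (adjusted p = 0.0563), Etfb (0.0650) and Decr1 (0.0684) had log2 differences of 0.94, 0.67 and 0.61. Of 37 nuclear-encoded respiratory chain subunits, 36 were positive and Cox7a1 (1.61-fold, adjusted p = 0.0321) and Cox6c (1.54-fold, adjusted p = 0.0391), subunits of cytochrome c oxidase, passed, with 17 past the threshold adjusted over the list alone (camera adjusted p = 8.67e-11; adjusted p = 0.348 with an estimated correlation). None of 25 genes of the citric acid cycle and pyruvate dehydrogenase passed over all genes, and 11 passed adjusted over the list alone (camera adjusted p = 6.91e-08; adjusted p = 0.345 with an estimated correlation). Cs, the citrate synthase gene, had a log2 difference of 0.54 and Sdha of 0.56. All 12 regulators of mitochondrial biogenesis were positive, none passed over all genes and 3 passed adjusted over the list alone (camera adjusted p = 2.12e-05; adjusted p = 0.345 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial genes, had 384 ± 47.2 CPM in the libraries labelled TAC and 209 ± 50.6 in those labelled Sham (adjusted p = 0.0643). Of 18 genes of branched-chain amino acid catabolism, Mccc1 passed (1.51-fold higher in the libraries labelled TAC) and 11 passed adjusted over the list alone, 10 of them in that direction (camera adjusted p = 4.21e-05; adjusted p = 0.386 with an estimated correlation).

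Of 18 adult sarcomere genes, 14 were positive, none passed over all genes and 1 passed adjusted over the list alone, Tnni3, the cardiac troponin I gene (log2 difference 0.63, adjusted p = 0.0568). The list was past the threshold with a preset correlation (camera adjusted p = 0.0395; adjusted p = 0.558 with an estimated correlation), but not without the libraries labelled TAC 1 (0.185), Sham 1 (0.0531) or Sham 3 (0.250), nor with quantile normalization (0.0944) or the replicate number as a block (0.0636). Of 14 calcium handling genes, 13 were positive, none passed over all genes and 3 passed adjusted over the list alone (camera adjusted p = 0.00438; adjusted p = 0.558 with an estimated correlation, and 0.0577 without the library labelled TAC 1). Of 18 ion channels and connexins, 14 were positive and none passed over all genes, while 7 passed adjusted over the list alone, 6 of them higher in the libraries labelled TAC (camera adjusted p = 0.000477; adjusted p = 0.345 with an estimated correlation). Kcnv2, a potassium channel subunit, had 16.2 ± 3.94 CPM in the libraries labelled TAC and 5.01 ± 2.17 in those labelled Sham (adjusted p = 0.0566).

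**Figure D2:**
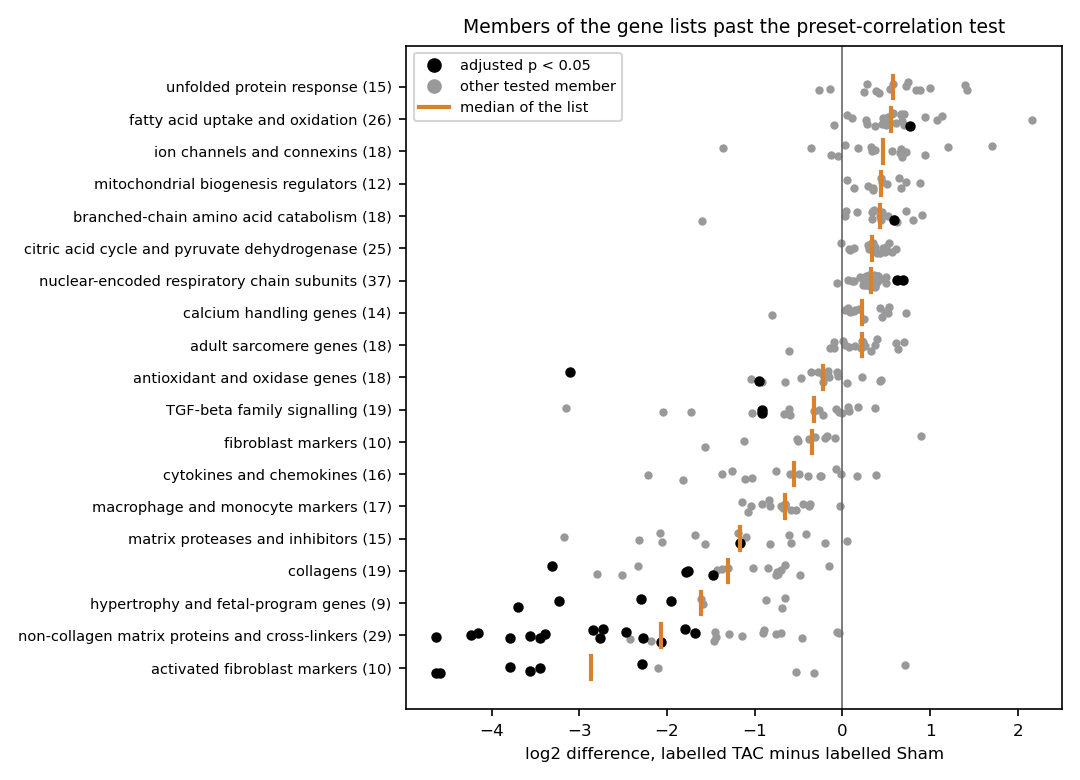
Log2 difference, labelled TAC minus labelled Sham, of each tested member of the 19 gene lists past the threshold with a preset correlation, with the number of tested members in brackets. Black points passed an adjusted p of 0.05 over all genes and the orange bar is the list's median, which runs from -2.87 for activated fibroblast markers to 0.57 for the unfolded protein response.

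None of 17 macrophage and monocyte markers passed over all genes, all 17 had a negative log2 difference, and 7 passed adjusted over the list alone (median -0.66, camera adjusted p = 3.17e-07; adjusted p = 0.373 with an estimated correlation). Ctss, the cathepsin S gene, had 27.1 ± 5.01 CPM in the libraries labelled Sham and 13.2 ± 3.41 in those labelled TAC (adjusted p = 0.0672). In the list of antioxidant and oxidase genes, 2 of 18 passed, Nox4, an NADPH oxidase gene (8.65-fold), and Sod3, the extracellular superoxide dismutase gene (1.93-fold), both higher in the libraries labelled Sham, and 4 passed adjusted over the list alone, 3 of them in that direction (camera adjusted p = 0.0106; adjusted p = 0.373 with an estimated correlation). None of 16 cytokines and chemokines passed over all genes and 1 passed adjusted over the list alone (median -0.55, camera adjusted p = 0.0121; adjusted p = 0.453 with an estimated correlation, and 0.250 without the library labelled Sham 3). The 15 genes of the unfolded protein response included none that passed, over all genes or over the list alone. That list was past the threshold in camera toward the libraries labelled TAC (adjusted p = 0.0304; 0.789 with an estimated correlation), and its mean was 6.50 log2 CPM in the library labelled TAC 3 and between 4.96 and 5.41 in the other 5. Its adjusted p was 0.988 with the opposite sign without the library labelled TAC 3, 0.207 without Sham 1 and 0.0679 with quantile normalization.

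The other 20 lists tested did not pass with a preset correlation. They held markers of endothelial cells (13 genes, median log2 difference -0.03), pericytes and smooth muscle (11, -0.06), mesothelium (7, -0.19), lymphocytes (5, 0.64), neutrophils (4, 1.73), nerve (7, 0.43) and atrium (4, -0.70). They also held erythroid (5, 0.49), cell cycle (14, 0.26), interferon-stimulated (19, -0.19), heat shock (13, -0.07), autophagy and atrophy (15, -0.04), circadian (16, -0.03), immediate early (12, -0.07), ribosomal protein (28, 0.04), histone (8, 0.08) and mitochondrially encoded genes (13, 0.24), hormone and adrenergic receptors (16, 0.05), glycolysis genes (24, 0.01) and known lncRNAs (25, 0.05). Without the library labelled TAC 3, atrial markers (camera adjusted p = 5.40e-06), immediate early (0.000394), heat shock (0.00159) and interferon-stimulated genes (0.0305) passed toward the libraries labelled Sham. In that fit erythroid genes (5.46e-07), neutrophil markers (0.000616) and mitochondrially encoded genes (0.00160) passed toward those labelled TAC. The 4 neutrophil markers averaged 2.32, 0.34 and -1.38 log2 CPM in TAC 1, 2 and 3. In Sham 1, 2 and 3 they averaged -0.46, -0.55 and 0.26, so their result rested mainly on TAC 1. Atrial markers (0.00969) and interferon-stimulated genes (0.0302) also passed without Sham 2, and immediate early (0.0335) and mitochondrially encoded genes (0.0444) without Sham 1, each in the same direction. Erythroid genes passed toward the libraries labelled TAC with limma on log2(FPKM + 1) (0.0446) and with the replicate number as a block (0.0465), and mitochondrially encoded genes passed with the former (0.0246) and had the opposite sign with quantile normalization (0.933). In the lists of receptors, glycolysis genes, endothelial markers, histone genes, lymphocyte markers and known lncRNAs, the median, the mean and the tests differed in sign. Slc2a1, the glucose transporter GLUT1 gene, was the 1 glycolysis gene that passed (log2 difference -0.88, adjusted p = 0.0488). Among known lncRNAs counted in the gene table, Dnm3os passed and was 2.39-fold higher in the libraries labelled Sham (adjusted p = 0.0480), while H19 (log2 difference 1.35, adjusted p = 0.0528), Mir22hg (-0.80, 0.0552) and Pvt1 (-1.15, 0.0646) did not.

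The genes higher in the libraries labelled TAC had smaller differences. Of these 49 genes, 22 had predicted, clone or pseudogene names. Among the others the largest differences were those of Cenpf, a kinetochore protein gene (3.84-fold, log2 difference 1.94, SE 0.33), Lgals4, the galectin-4 gene (3.78-fold), and Ces1d, a carboxylesterase gene (3.50-fold). Bhlhb9 (2.91-fold), Emilin2 (2.48-fold), Slc16a7, a monocarboxylate transporter gene (2.11-fold), Ppp1r3b, a glycogen-targeting phosphatase subunit gene (2.08-fold), Celsr1 (2.08-fold), Fam212b (2.07-fold) and Adhfe1 (2.01-fold) completed the 10 largest, with edgeR adjusted p-values from 0.0280 to 0.0488. The list of 14 cell cycle genes did not pass, nor did any of its members.

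In the lncRNA table, 17 of 16035 transcripts tested passed an adjusted p of 0.05, 8 higher in the libraries labelled TAC and 9 higher in those labelled Sham. With the libraries split 3 against 3 in other ways, the same test called between 3 and 15 transcripts. The labelled groups therefore gave few more calls than arbitrary groups. Of the 17, 13 had at least 50 scaled counts in their highest library and stood in each library either above 1/5 or below 1/20 of that value. The transcript NONMMUT053361.2 (chromosome 5, 101832955 to 101834962 on GRCm38, overlapping Wdfy3) had 360, 401 and 341 counts in the libraries labelled TAC and 1 in each labelled Sham, a ratio of 365 after scaling (95% interval 124 to 1770 from counting error alone). NONMMUT006148.2 (chromosome 10, 71225464 to 71229120, inside Tfam, the gene of a mitochondrial transcription factor) had 333, 318 and 222 counts against 1 in each, a ratio of 289 (98.5 to 1400). The other 3 largest rises were NONMMUT029155.2 inside Zfp799 (log2 difference 5.65, SE 0.33), NONMMUT066583.2 inside Cyld (5.48, SE 0.24) and NONMMUT069663.2 inside Fbxl22 (4.99, SE 0.44). The largest falls were NONMMUT024403.2 inside Poldip3 (-7.12, SE 0.33), NONMMUT035305.2 inside Cacul1 (-7.11, SE 0.23), NONMMUT005863.2 inside Kif1bp (-6.63, SE 0.29), NONMMUT049857.2 inside Phactr4 (-6.50, SE 0.23) and NONMMUT039394.2 inside Mga (-5.85, SE 0.65).

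As a set, the overlapping genes compared with these lncRNAs did not follow them. Of the 17 transcripts, 16 overlapped a gene of the gene table, as did 79.6% of the transcripts tested and not called. Where a transcript overlapped several genes, only the gene with the most counts was compared. The median log2 difference of the 16 genes compared, taken in the direction of their lncRNA, was 0.02 (SE 0.10 over genes), against 5.65 for the lncRNAs. Zfp799 was the 1 gene of these 16 that passed (log2 difference 0.76, adjusted p = 0.0329). Fbxl22 had the largest difference of them without passing (log2 difference 1.14, SE 0.295, adjusted p = 0.101). Both differed in the direction of their lncRNA. Tfam had 39.0 CPM in the libraries labelled TAC and 35.7 in those labelled Sham, and Wdfy3 170 and 182. Whether the counting used strand is not given in the sources used here, so reads of a lncRNA and of an overlapping gene cannot be told apart by strand. The count of 17 was 29 without the library labelled TAC 2 and 31 without TAC 3, and DESeq2 called 224.

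**Figure D3:**
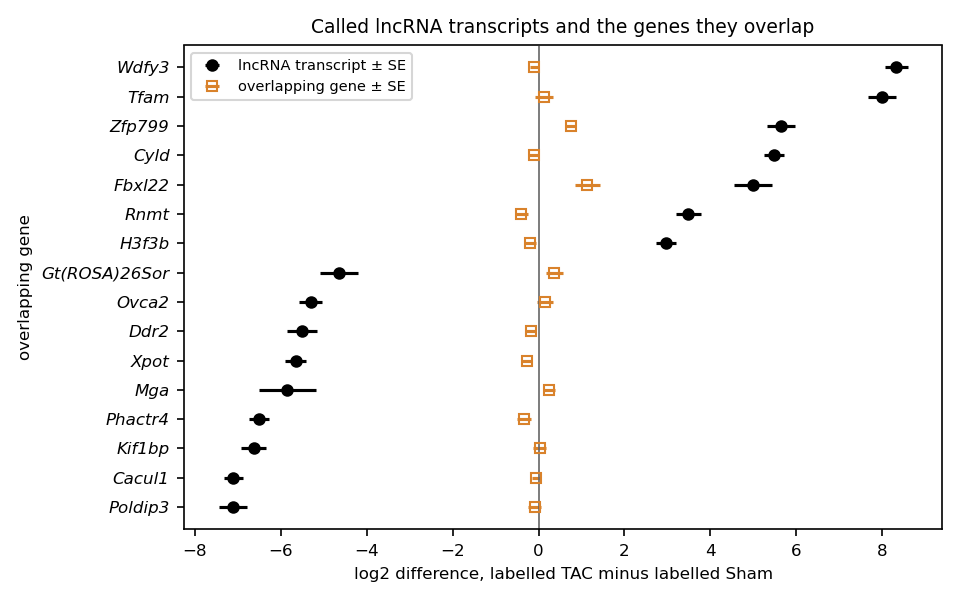
Log2 difference, labelled TAC minus labelled Sham, of the 16 called lncRNA transcripts that overlap a gene (black, with SE). The gene drawn for each is the overlapping gene with the most counts (orange, with SE). The lncRNAs lie between -7.12 and 8.34, while Zfp799 and Fbxl22 are the 2 drawn genes above 0.5.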

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

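The count of 217 genes stayed within 1.5 times with both other pseudocounts, an FPKM minimum of 0.1, median-of-ratios scaling, totals without mitochondrial genes, a 2-fold minimum and limma with a trend, without it or with a robust fit. It was 432 without a filter, 73 at a mean FPKM of at least 5 (fewer genes tested), 129 with quantile normalization, 885 with array weights, and, in alternatives chosen after seeing the data, 1195 with DESeq2 and 338 without TMM. Leaving out 1 library gave 0 to 397 genes. No called gene changed sign where these tested it (84 of the 217 at a mean FPKM of at least 5, 168 with limma, 217 in the others). The 17 lncRNAs became 4 at a mean FPKM of at least 5, 224 with DESeq2 and 18 to 31 with 1 library left out. 4 limma settings and the totals without mitochondrial genes put the median log2 difference of all lncRNAs at 0.11 to 0.15. With the replicate number as a block, 41 genes and 11 lncRNAs passed. Deviations of libraries with the same number correlated at -0.14, -0.12 and -0.10, no library correlated best with its own number, and the numbers were not taken as pairs. The 19 gene lists past the threshold fell to 0 with an estimated correlation and were 16 to 25 with 1 library left out. The adjusted p of the unfolded protein response list ran from 8.92e-06 to 0.988 with 1 library left out, with the sign turned without TAC 3. The log2 difference of Myh7 ran from -4.61 to 0.12 and that of Manf from -0.0933 to 1.87, and Manf stood at -0.00803 with array weights. The cause was not tested, except where fewer genes or libraries entered. Of 766 comparisons of the 37 called genes under the naming rule with an alternative, 512 stayed past the threshold and 254 did not, and all 37 missed it without TAC 1. Of 999 comparisons of the 49 other genes under that rule, 885 kept their side of the threshold, 111 passed it and 3 turned sign, and of 202 of the 10 named lncRNAs 182 stayed past it. In the simulated data, no 2-fold change of lncRNAs was recovered.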

Other observations

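Gene groups outside the fixed lists were read from the KEGG terms of the deposited table, chosen after seeing the data. Among the 75 genes with a KEGG term that were higher in the libraries labelled Sham, complement and coagulation held 6 of 42 tested members against 0.586 by chance (one-sided Fisher test, adjusted p = 0.000912). The smallest adjusted p (0.000141) was that of the malaria term, with 7 of 36, mostly matrix and adhesion genes. Among the complement genes were C4b (2.70-fold), C7 (2.73-fold), Cfb (5.05-fold, and 7.76-fold with an adjusted p of 0.0577 without the library labelled TAC 1), Masp1 (2.18-fold) and Serping1 (1.79-fold). The term for allograft rejection held 5 of 20 (adjusted p = 0.000594), namely the class I histocompatibility genes H2-K1 (1.89-fold), H2-Q4, H2-Q6 and H2-T22 and the costimulatory gene Cd80. H2-Q4 and H2-Q6 have near-identical relatives, so their counts are uncertain. The H2 genes named, C4b and Cfb all lie on chromosome 17 between 33996017 and 36042747, while the Fisher test treats genes as independent. The complement and allograft terms are therefore not fully separate results. Tlr4, a receptor of innate immunity, was 6.66-fold higher in the libraries labelled Sham. In the other direction the term nearest the threshold was valine, leucine and isoleucine degradation with 3 of 47 (Aldh9a1, Hadh and Mccc1, adjusted p = 0.0506).

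For 3 patterns technical explanations were weighed. The tests of exchanged labels, of the genes overlapping lncRNAs and of the library labelled TAC 3 were chosen after the results were seen. The tests of atrial tissue, of switching read assignment and of other splits were set before.

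Several genes that rise in heart failure, such as 4 of 9 hypertrophy genes and 4 of 19 collagens but neither Nppb nor Myh7, passed toward the libraries labelled Sham (for the hypertrophy list, adjusted p = 0.31 with an estimated correlation), and an exchange of 1 library of each group is argued against, since all 3 libraries labelled Sham had a mean over the 4 lists of hypertrophy, collagen, matrix and activated fibroblast genes (7.08, 7.88 and 7.22 log2 CPM) above that of all 3 labelled TAC (5.48, 5.43 and 5.33). Atrial tissue in the libraries labelled Sham is argued against as the source of the whole difference of Nppa. The median log2 difference of 4 other atrial markers was -0.70 (SE 0.27 over markers, not libraries) against -3.70 for Nppa. Their mean was 3.50, 0.24 and 3.59 log2 CPM in Sham 1, 2 and 3 and -1.01, 0.89 and 3.53 in TAC 1, 2 and 3. Nppa did not follow that mean, with 772, 1894 and 595 CPM in Sham 1, 2 and 3 and 92.2, 64.3 and 95.1 in TAC 1, 2 and 3. The marker list passed toward the libraries labelled Sham without TAC 3 (camera adjusted p = 5.40e-06) and without Sham 2 (0.00969). A part from atrial tissue in single libraries therefore stays open. The hypothesis that the labels or library codes of all 6 libraries are exchanged between the groups and that of lower expression of these genes after the operation, as the labels have it, stay open and cannot be told apart: 4 of the 4 lists were higher in each library labelled Sham than in each labelled TAC, but that observation raised the question and does not test it.

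Of the 17 called lncRNA transcripts, 13 had at least 50 scaled counts in their highest library and were on (above 1/5 of it) or off (below 1/20) in every library. A change of the overlapping gene is argued against by the median log2 difference of 0.0163 (SE 0.101) over 16 such genes, 1 per transcript. Other genes that overlapped the same transcripts were not compared. Switching of read assignment between overlapping transcripts from library to library may account for the pattern, but read assignment itself was not examined. The counts that follow cannot tell such switching from other differences between single libraries. Of 534 transcripts that were on in some libraries and off in others, 15 or 2.81% followed the labelled groups, which only the 93 that were on in 3 libraries could do, and each of the 9 other splits of 3 against 3 libraries held 7 to 13. Such transcripts were 6.16% of the lncRNAs at that minimum and 0.253% of the genes. Of the 534, 448 overlapped a gene, as did 12748 of the 16018 transcripts tested and not called (79.6%). These sets were not matched on expression, so no excess of overlap is read from them.

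Myh7 stood at 6050 CPM in the library labelled TAC 3 and at 212 and 65.7 in those labelled TAC 1 and 2. RNA of a heart like those labelled Sham is argued against. The 62 other members of the 4 lists had a median log2 difference of -0.49 (SE 0.12 over genes) between TAC 3 and the mean of TAC 1 and 2. Of 4 skeletal muscle markers, Acta1 (-2.14) and Myl1 (-1.96) were lower in TAC 3, and Tnnt1 (-0.24) and Atp2a1 (0.03) differed little. Atp2a1 was near the floor, at 0.66 CPM in TAC 3, and Acta1 is also 1 of the 62 genes. Skeletal muscle tissue is argued against too by the median of these markers, -1.10 (SE 0.57 over markers), which rests on Acta1 and Myl1. These SEs do not cover the spread between libraries, since they concern the single library TAC 3. Of genes of the unfolded protein response, Hspa5 had 1172 CPM there against 405 and 267 and Manf 133 against 26.8 and 14.2, and the list's median (1.31) lay at percentile 100 of 10000 random lists matched on expression. The list was taken for this test after it was seen to stand apart in TAC 3, so the percentile does not support a stress response of this heart that differs from the other libraries labelled TAC, and that explanation stays open.

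The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The labelled split called 217 genes, and the highest of the others 1. It called 17 lncRNAs, and the highest of the others 15. In both tables no other split gave as many calls as the labelled split, but the margin was wide for genes and narrow for lncRNAs. Each other split put libraries of both labels on both sides. A difference between the labelled groups then adds to the spread within each side and lowers the calls. The wide margin for genes is therefore not a measure of false calls.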
